A study of Homo sapiens with 8 samples.

How the data were processed

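Total RNA from GBM14 cells, a human glioblastoma cell line, was labelled with biotin and hybridised to Affymetrix arrays, per the labels. The cells had been treated for 24 h with DMSO, with 10 µM ONC206, with 2.5 nM romidepsin or with both drugs, and each of the 4 groups had 2 arrays. Each array was put in its group by the treatment in its sample title. The deposited values are log2 expression values made by the authors with robust multi-array average (RMA) in R 3.6.0 with affy 1.62.0, per the submitters' processing notes. RMA subtracts background, gives all arrays 1 common distribution of probe intensities and summarises the probes of a probe set on the log2 scale, so a change shared by most genes would be removed and small changes of dim genes are compressed. The array design and the genome build behind the probe sets are not given in the sources used here, and no coordinates are printed. The table holds no detection calls. Where the lower of the compared group means of a named gene past the threshold lay under the median DMSO level of all genes (3.38), its fold or log2 change between groups is given as at least that size. That median is not a background level. Folds with a lower mean just above it, as for OAS2 with romidepsin (3.41), may be bounded by the floor as well. Interactions and list medians are given as measured. The values ran from 0.0354 to 12.4. The medians of the array columns were 3.43 and 3.33 for DMSO, 3.37 and 3.38 for ONC206, 3.37 and 3.40 for romidepsin, and 3.42 and 3.42 for the combination.

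The table held 29597 probe sets. A gene symbol came from the platform annotation deposited with GEO, brought up to date through its Entrez identifier with the RefSeq gene table of GRCh38.p14, which replaced 0 symbols. In all, 28556 probe sets had 1 symbol, 0 had several and 1041 were unnamed here. Where a symbol had more than 1 probe set, which was so for 3 symbols, the probe set with the highest mean over the 8 arrays was kept. This left 28553 genes, of which 17835 were protein-coding and 7511 were long non-coding RNAs in the RefSeq table. The table held 0 Affymetrix control probe sets, and no filter on dim genes was applied. A probe set identifier, such as that of DDIT4 (54541_at), is given in parentheses at the first mention of a gene chosen by rule for the ONC206 comparison.

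The fit, the samples in it, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined. limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 8 arrays (lmFit) and moderated the variances (eBayes, defaults), with 4 residual and 3.51 prior degrees of freedom. There were 6 contrasts: ONC206 against DMSO, romidepsin against DMSO, the combination against DMSO, against romidepsin and against ONC206, and the interaction. The interaction is the ONC206 change in romidepsin-treated cells minus the ONC206 change in DMSO-treated cells, and it is 0 where the log2 changes of the drugs add up. Tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. Adjusted p-values of genes are from this limma fit. A fold change is 2 to the power of the log2 change, and its standard error (SE) is given on the log2 scale.

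Of 34 gene lists drawn up from general knowledge, 32 were tested. The list of transcripts encoded by mitochondrial DNA had no measured member, and the list of drug targets and readouts was read gene by gene only. Of 1033 list memberships, 949 (91.9%) were measured. Each list was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 32 lists within a contrast. Camera was also run with the correlation estimated from the arrays, and fry was run beside it. Of the camera calls, 6 of 15 held with an estimated correlation for ONC206, 1 of 15 for romidepsin, 1 of 17 for the combination against DMSO, 0 of 2 against romidepsin, 0 of 18 against ONC206 and 6 of 12 for the interaction. Counts of list members were made over all genes tested and, separately, adjusted over the list alone. Some lists share genes, such as 4 between p53 targets and pro-apoptotic genes, and 2 between p53 targets and stress response targets. Lists of leukocyte, endothelial and pericyte markers served as checks for other cell types. The leukocyte markers were dim (median DMSO level 2.42, against 3.38 for all genes), so they could show a gain of such cells but hardly a loss.

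The rule named, per contrast, the 5 genes with the largest rise and the 5 with the largest fall among genes past the threshold, with both arrays of one group beyond both of the other (not asked of the interaction). It further named the 2 most changed members past the threshold of each core list for contrasts against DMSO, or 1 for the other contrasts, and all drug targets and readouts. Where no member passed, the member with the smallest p was named. Symbols of uncharacterised loci, small, intergenic or antisense RNAs, olfactory receptors and immune receptor segments were not named, and Y-linked genes are not reported. RFPL4AL1 met the rule for 3 contrasts and is not reported as a single gene, since near-identical copies share its sequence. Genes named outside the rule are said to have been chosen after their values were seen.

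The fold changes of the single drugs share the DMSO arrays. Their correlation, covariance and share of equal signs were therefore set beside 100 simulations of unchanged groups measured against shared controls. The overlap of calls was set beside the number for independent lists, which takes every gene as equally likely to be called. Romidepsin calls were commoner among genes of higher expression, so that number is low as a reference. A split of the controls, added after the data were examined, gave 1 DMSO array to each of the contrasts compared, in both ways, in a limma fit with each DMSO array as its own group.

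The steps were tested on simulated data, in 5 simulations of all 28553 genes with the DMSO means in every group and variances drawn from the fitted prior. For ONC206 against DMSO, 1.19% of simulated changes of 0.5 log2 were recovered, 46.9% of changes of 1 and 95.2% of changes of 2, with 3.4 false calls per simulation. For the interaction, the recovery was 0%, 5.07% and 74.5%, with 2.8 false calls. Camera called 5 of 5 simulated lists shifted by 0.5 and 0 of 150 lists without a shift. The simulated genes varied independently of each other, so this cannot show how often lists of correlated genes are called without a shift.

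The alternatives were centring each array on its median, quantile normalization again, removal of dim genes (mean log2 value up to 2.51), the mean of a gene's probe sets, all probe sets, eBayes with trend and robust fitting, a fit of the compared groups alone, the replicate number as a block, each array left out in turn, and a required log2 change of at least 1. A group left with 1 array was assumed to vary like the others. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Probe sets unnamed here were tested only as the alternative with all probe sets.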

Results

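Gene expression was measured in GBM14 cells, a human glioblastoma line, on 8 Affymetrix arrays after 24 h of drug treatment. The 4 groups of 2 arrays each received DMSO as vehicle, 10 µM ONC206, 2.5 nM romidepsin, or both drugs together. ONC206 is known as an agonist of ClpP, a protease of the mitochondrial matrix, and romidepsin inhibits the histone deacetylases HDAC1 and HDAC2. The number of arrays limits the precision: the median SE of a log2 fold change was 0.15 over 28553 genes, and 0.22 for the interaction of the drugs. The labels do not say that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. Replicate arrays correlated across genes at r = 0.991 in every group, where genes are not independent replicates. Arrays with and without romidepsin correlated at 0.956 to 0.961, DMSO with ONC206 arrays at 0.986 to 0.988, and romidepsin with combination arrays at 0.988 to 0.989.

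The first comparison asked what ONC206 does alone. Targets of ATF4, the transcription factor of the integrated stress response to mitochondrial, endoplasmic reticulum and amino acid stress, rose. Of 53 measured targets, 42 rose and 11 did not pass, and adjusted over the list alone 48 rose and 1 fell, with a median log2 change of 1.20 (camera, adjusted p = 1.07e-66, and 0.00698 with an estimated correlation). DDIT4 (54541_at), an inhibitor of the growth kinase complex mTORC1, rose 19.7-fold, a log2 change of 4.30 ± 0.13 (SE, n = 2 arrays per group; adjusted p = 7.6e-05). GDF15 (9518_at), a secreted stress hormone, rose 12.1-fold (3.59 ± 0.22), and SESN2 (83667_at), a sensor of leucine, rose 9.50-fold (3.25 ± 0.20). TRIB3 (57761_at), a pseudokinase that restrains ATF4 signalling, rose 8.13-fold (3.02 ± 0.20), and DDIT3 (1649_at), the pro-apoptotic factor CHOP, rose at least 6.74-fold (2.75 ± 0.17). INHBE (83729_at), which encodes an activin subunit, lay outside the list and rose 14.3-fold (3.83 ± 0.17). ATF4 itself (468_at) had a log2 change of 0.66 ± 0.15 that did not pass (adjusted p = 0.0956).

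Targets of NRF2, the factor of the antioxidant response, and interferon-stimulated genes were higher as well. Of 24 NRF2 targets, 17 rose (20 adjusted over the list alone), with a median log2 change of 0.85 (adjusted p = 4.08e-27, and 0.0108 with an estimated correlation). Of 39 interferon-stimulated genes, 19 rose (37 adjusted over the list alone), with a median of 1.01. IFIT2 (3433_at) and IFIT3 (3437_at), antiviral proteins that bind foreign RNA, rose by log2 changes of 1.87 ± 0.18 and 1.51 ± 0.23. The camera test of the interferon list (adjusted p = 7.51e-39) was lost with an estimated correlation (adjusted p = 0.0709), and the other 13 alternatives gave at most 1.05e-29. Leukocyte markers, which could bring such genes with other cells, had a median log2 change of -0.01, endothelial markers -0.07 and pericyte markers -0.05. HLA class I and antigen processing genes had a median of 0.36 and were called as a list (adjusted p = 2.68e-07), while limma called 0 of 15 members, with 9 at an unadjusted p under 0.05 and 7 higher adjusted over the list alone.

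Cell cycle genes fell. Of 59 genes of G2/M and mitosis, 25 fell and 34 did not pass (53 fell adjusted over the list alone), with a median log2 change of -0.65 (adjusted p = 6.53e-45, and 0.0287 with an estimated correlation). Of 46 genes of DNA replication and S phase, 14 fell (41 adjusted over the list alone), with a median of -0.59 (adjusted p = 2.13e-36, and 0.034 with an estimated correlation). CCNE2 (9134_at), a cyclin of S-phase entry, had a log2 change of -1.38 ± 0.12, MKI67 (4288_at), the proliferation marker Ki-67, -1.15 ± 0.11, and CLSPN (63967_at), a mediator of the replication checkpoint, -1.13 ± 0.19. KIF20A (10112_at), a kinesin of cytokinesis, had a change of -1.05 ± 0.11. The largest falls of named genes were those of RGS4 (5999_at), a brake on G-protein signalling, at -1.83 ± 0.13, FAM111B (374393_at) at -1.59 ± 0.13, LRRC17 (10234_at) at -1.51 ± 0.14 and STC1 (6781_at), a secreted glycoprotein, at -1.50 ± 0.24.

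With ONC206, CLPP (8192_at) had a log2 change of -0.03 ± 0.12 (adjusted p = 0.949) and its partner CLPX (10845_at) 0.21 ± 0.11 (adjusted p = 0.506). Of 19 mitochondrial chaperones and proteases 3 rose (5 adjusted over the list alone), among them LONP1 (9361_at), another matrix protease, by 0.88 ± 0.11 and GRPEL2 (134266_at), a co-chaperone of matrix HSP70, by 0.70 ± 0.11. limma called 0 of 69 nuclear-encoded respiratory chain and ATP synthase subunits (7 at an unadjusted p under 0.05) and 0 of 72 mitochondrial ribosomal proteins (2 at an unadjusted p under 0.05). Their members with the smallest p were NDUFB3 (4709_at) at -0.44 ± 0.13 and MRPS6 (64968_at) at -0.48 ± 0.12. Transcripts encoded by mitochondrial DNA were not analysed here. Of 29 endoplasmic reticulum chaperones and XBP1 or ATF6 targets, 1 rose and 3 fell (3 and 7 adjusted over the list alone). XBP1 (7494_at), a factor of the unfolded protein response, rose by 0.99 ± 0.11, and MANF (7873_at), a secreted protein of the endoplasmic reticulum, fell by 0.87 ± 0.11.

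Among the remaining lists, p53 targets had 4 of 28 members higher (8 adjusted over the list alone), 2 of which are also stress response targets, and the median was 0.23 (adjusted p = 5.12e-07, and 0.0287 with an estimated correlation). In the pro-apoptotic list of 22 genes, TNFRSF10B (8795_at), the death receptor DR5, was the only gene past the threshold, higher by 0.69 ± 0.12. Its call ended whichever array was left out. At an unadjusted p under 0.05 (limma), 4 members of this list were higher and 2 lower. Homologous recombination genes had 2 of 20 lower (12 adjusted over the list alone; median -0.47), and replication-dependent histones 3 of 42 (18 adjusted over the list alone; median -0.39). Camera called both lists, but not with an estimated correlation (adjusted p = 0.0784 and adjusted p = 0.157). The same holds for cholesterol synthesis (1 of 18 lower, 6 adjusted over the list alone; adjusted p = 0.243 with an estimated correlation), autophagy and lysosome genes (1 of 27 higher, 3 adjusted over the list alone; adjusted p = 0.279), and cytosolic heat shock genes (1 of 20 lower; adjusted p = 0.146). Mitochondrial chaperones (adjusted p = 0.157), endoplasmic reticulum chaperones (adjusted p = 0.243) and the tricarboxylic acid cycle list (adjusted p = 0.243) also lost their calls in this way. MYC (4609_at) rose by 0.72 ± 0.11 as the only 1 of 29 MYC and ribosome biogenesis genes past the threshold. The MYC call ended whichever array was left out. Of 40 neuronal genes, UCHL1 (7345_at), a neuronal deubiquitinase, rose by 0.73 ± 0.10 and SNAP25 (6616_at), a synaptic vesicle fusion protein, fell by 0.75 ± 0.11. Among 29 genes known to rise under HDAC inhibition, 1 rose, GADD45B (4616_at), by 0.88 ± 0.11 (5 rose and 3 fell adjusted over the list alone), and 1 of 29 glial and neural progenitor genes fell.

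In the other lists limma called 0 members for ONC206. The counts at an unadjusted p under 0.05 were 3 of 23 for the tricarboxylic acid cycle, 2 of 24 for fatty acid oxidation, 4 of 21 for glycolysis, 1 of 13 for anti-apoptotic genes, 3 of 18 for histone deacetylases and sirtuins and 7 of 43 for mesenchymal and matrix genes. They were 0 of 9 for metallothioneins, 0 of 19 for leukocyte, 0 of 14 for endothelial and 1 of 11 for pericyte markers, and 1 of 14 for housekeeping genes. The drug targets HDAC1 (3065_at), HDAC2 (3066_at) and HDAC3 (8841_at) had log2 changes of -0.15, -0.16 and -0.02, DRD2 (1813_at), a dopamine receptor, 0.32, and PPARGC1A (10891_at), a regulator of mitochondrial biogenesis, -0.14, none of which passed. The cyclin-dependent kinase inhibitor CDKN1A (1026_at) had a change of 0.62 ± 0.12 (adjusted p = 0.0645), LDHA (3939_at), lactate dehydrogenase, -0.59 ± 0.11 (adjusted p = 0.055), BIRC5 (332_at), the apoptosis inhibitor survivin, -0.49 ± 0.12 and CCN1 (3491_at), a matrix signalling protein, 0.48 ± 0.11.

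In total 406 of 28553 genes passed for ONC206, 262 higher and 144 lower, of which 165 changed at least 2-fold. The count rested on every array. It was 55 and 70 without the first or the second DMSO array, 59 and 52 without either ONC206 array, 241 without either romidepsin array and 190 without either combination array. Of the 25 named genes past the threshold, 9 passed in all of these fits, and the highest adjusted p of the other 16 was 0.22. The calls of TNFRSF10B, MYC, GRPEL2 and SNAP25 ended in all 8 of these fits, and those of STC1 and IFIT3 in 7. Of the 15 lists called by camera, 5 lost their call in at least 1 other alternative. The removal of 1 DMSO array ended that of endoplasmic reticulum chaperones (adjusted p = 0.183), mitochondrial chaperones (0.0968), heat shock genes (0.113), the tricarboxylic acid cycle (0.278) and autophagy genes (0.0581). The heat shock call also ended without the first ONC206 array (0.085), and the tricarboxylic acid cycle call in 11 of 13 alternatives, every single array but the first DMSO array among them.

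**Figure D1:**
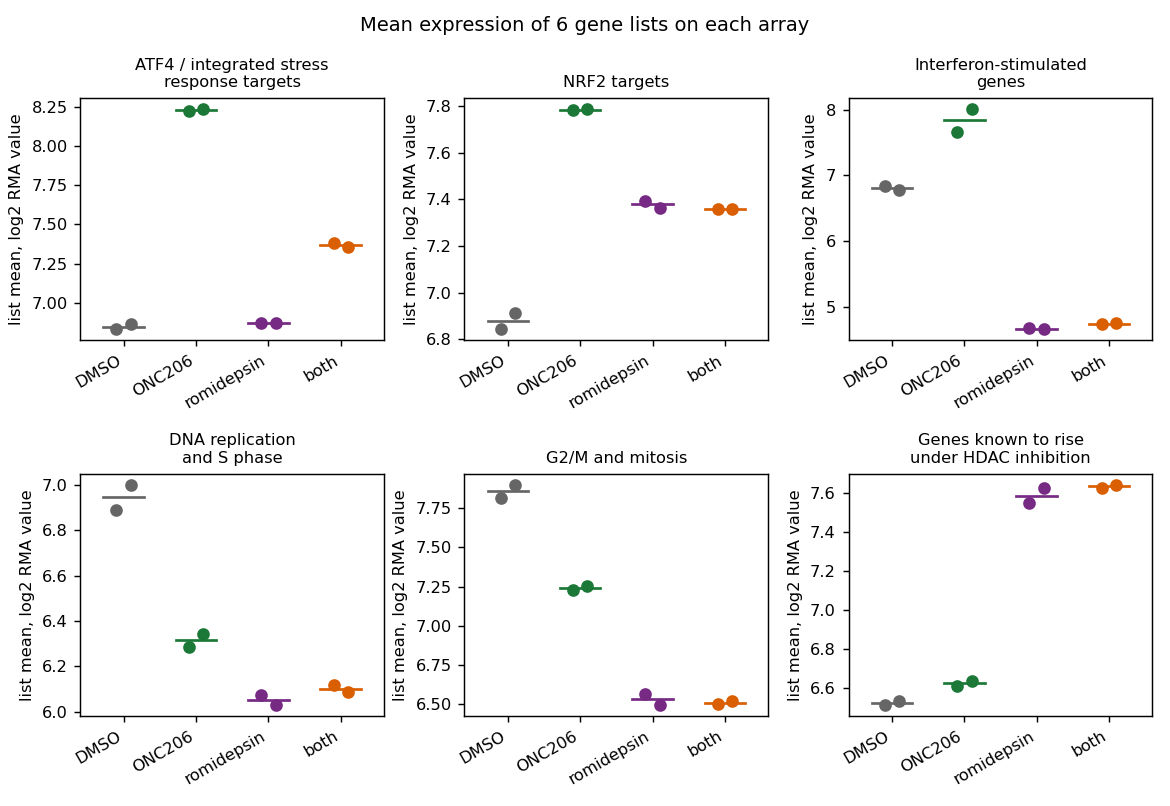
Mean log2 RMA value of the measured members of 6 gene lists (vertical axes) in the 4 treatment groups (horizontal axes), with 1 dot per array and a line at the mean of the 2 arrays. Stress response targets, NRF2 targets and interferon-stimulated genes were highest on the ONC206 arrays, where their median log2 changes against DMSO were 1.20, 0.85 and 1.01, and interferon-stimulated genes were lowest on the romidepsin and combination arrays.

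The second comparison asked what romidepsin does alone. By median log2 change, the fixed list that fell furthest was that of interferon-stimulated genes, of which 33 of 39 fell (34 fell and 1 rose adjusted over the list alone), with a median log2 change of -2.15. The OAS2 transcript, which encodes a sensor of double-stranded RNA, was 23.6-fold lower (-4.56 ± 0.16), IFIT3 at least 23.9-fold lower (-4.58 ± 0.23, to a romidepsin mean of 1.67), and MX1, an antiviral GTPase, 18.0-fold lower (-4.17 ± 0.28; adjusted p = 7.63e-05). IFI44L (at least 4.43 lower, ± 0.14, to a romidepsin mean of 2.55) and XAF1 (-3.93 ± 0.14), likewise induced by interferon, were among the 5 named falls. HLA class I and antigen processing genes had 8 of 15 members lower and 2 higher (8 and 2 adjusted over the list alone; median -0.65). Leukocyte markers had a median of -0.10 with 1 of 19 lower, endothelial markers 0.02 with 1 of 14 lower, and pericyte markers 0.25 with 4 of 11 higher and 1 lower. With an estimated correlation the interferon and HLA calls were both lost (adjusted p = 0.133 for each).

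Proliferation genes fell further than with ONC206 in size, without a test between the drugs. Of 59 genes of G2/M and mitosis 55 fell (57 adjusted over the list alone; median -1.35; adjusted p = 0.0995 with an estimated correlation). Of 46 genes of DNA replication and S phase 34 fell and 2 rose (36 and 2 adjusted over the list alone; median -0.99; adjusted p = 0.133 with an estimated correlation). TYMS, thymidylate synthase, was 11.5-fold lower (-3.52 ± 0.16), and GINS3, part of the replicative helicase, 3.67-fold lower (-1.88 ± 0.14). The mitotic kinase PLK1 (-2.10 ± 0.12) and the kinetochore protein NDC80 (-2.07 ± 0.15) were 4.28-fold and 4.19-fold lower. Homologous recombination and Fanconi anaemia genes had 14 of 20 lower and 1 higher (15 and 1 adjusted over the list alone; median -0.73; adjusted p = 0.133 with an estimated correlation). Replication-dependent histones had 22 of 42 lower and 4 higher (25 and 6 adjusted over the list alone; median -0.73; adjusted p = 0.239 with an estimated correlation). CDKN1A rose 2.75-fold (1.46 ± 0.12).

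Genes known to rise under HDAC inhibition rose in 21 of 29 cases and fell in 1 (22 and 2 adjusted over the list alone), with a median of 0.66, and this call held with an estimated correlation (adjusted p = 0.0474). DHRS2, a mitochondrial and nuclear reductase, rose at least 15.1-fold (3.92 ± 0.27), and CPA4, a carboxypeptidase first found as a gene induced by HDAC inhibition, rose 8.20-fold (3.04 ± 0.12). By the folds as measured, the largest rise of a named gene was that of STC1, 26.3-fold (4.72 ± 0.24; adjusted p = 3.11e-05). Other named rises were those of SLC17A7, a vesicular glutamate transporter, at least 22.6-fold (4.50 ± 0.17, from a DMSO mean of 3.26), TUFT1 at 20.1-fold (4.33 ± 0.11) and TUBB4A, a neuronal beta-tubulin, at 16.6-fold (4.05 ± 0.24). Of 40 neuronal genes 14 rose and 2 fell (15 and 2 adjusted over the list alone; median 0.32; adjusted p = 0.133 with an estimated correlation). SCG2, a granin of secretory vesicles, rose at least 7.39-fold and GRIA2, an AMPA receptor subunit, at least 5.76-fold.

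CLPP fell 2.12-fold with romidepsin (-1.08 ± 0.12; adjusted p = 0.000573), whereas CLPX (-0.16 ± 0.11) did not pass. HDAC3 rose 3.64-fold (1.86 ± 0.13) and HDAC1 1.59-fold (0.67 ± 0.12), while HDAC2 had a change of -0.02 ± 0.13. Histone deacetylases and sirtuins as a list had 7 of 18 higher and 2 lower (9 and 3 adjusted over the list alone), without a camera call (adjusted p = 0.0839). Mitochondrial lists went both ways without a camera call. Chaperones and proteases had 7 of 19 higher and 2 lower (8 and 2 adjusted over the list alone), with OMA1, the protease of the inner membrane stress pathway, up 3.25-fold and TIMM17A, an import channel subunit, up 2.23-fold. Respiratory chain and ATP synthase subunits had 11 of 69 higher and 7 lower (12 and 8 adjusted over the list alone), for example NDUFB3 at 1.13 ± 0.13 and NDUFA9 at -1.04 ± 0.10. Mitochondrial ribosomal proteins had 9 of 72 higher and 14 lower (13 and 19 adjusted over the list alone), with MRPL3 at -1.16 and MRPL15 at -1.11. PPARGC1A rose by 0.91 ± 0.21, a call that ended without any single DMSO or romidepsin array (adjusted p up to 0.106 without the first romidepsin array).

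Among metabolic lists, 14 of 23 tricarboxylic acid cycle genes rose and 4 fell (15 and 4 adjusted over the list alone; median 0.57; adjusted p = 0.133 with an estimated correlation). Glycolysis genes had 6 of 21 higher and 2 lower (9 and 3 adjusted over the list alone; adjusted p = 0.186 with an estimated correlation). SLC2A3, the glucose transporter GLUT3, rose 9.80-fold and ENO2, the neuronal enolase, 3.71-fold. Cholesterol synthesis and uptake had 11 of 18 higher (12 adjusted over the list alone; median 0.61; adjusted p = 0.146 with an estimated correlation). Autophagy and lysosome genes had 14 of 27 higher and 1 lower (14 and 2 adjusted over the list alone; median 0.46; adjusted p = 0.182 with an estimated correlation). NRF2 targets had 13 of 24 higher and 2 lower (13 and 4 adjusted over the list alone; median 0.47; adjusted p = 0.133 with an estimated correlation). Fatty acid oxidation had 6 of 24 higher and 3 lower without a camera call (adjusted p = 0.163).

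Stress response targets went both ways with romidepsin. Of the 53 measured, 12 rose and 14 fell (13 and 18 adjusted over the list alone), and the median of -0.07 was not called (adjusted p = 0.621). SLC7A5, the large neutral amino acid transporter, rose 5.53-fold (2.47 ± 0.11) and DDIT3 at least 2.84-fold, while NUPR1, a stress-induced chromatin protein, was 6.14-fold lower (-2.62 ± 0.14) and ATF4 had a change of -0.40 ± 0.15 that did not pass. Endoplasmic reticulum chaperones had 6 of 29 higher and 5 lower (7 and 5 adjusted over the list alone), with XBP1 4.30-fold lower (-2.11 ± 0.11) and ERN1, the kinase IRE1 that splices XBP1, at least 2.22-fold higher. Cytosolic heat shock genes had 6 of 20 higher and 2 lower (adjusted p = 0.0649), metallothioneins 4 of 9 higher and 1 lower (0.0697), and p53 targets 9 of 28 higher and 4 lower (0.151). Pro-apoptotic genes had 6 of 22 higher and 6 lower (0.862), with the death receptor FAS at -1.53 ± 0.17 and BID, a BH3-only protein, at -1.51 ± 0.14. Anti-apoptotic genes had 5 of 13 lower and 1 higher (6 and 1 adjusted over the list alone; median -0.33; adjusted p = 0.133 with an estimated correlation). CFLAR, which blocks caspase-8, was lower by at least 2.32 ± 0.14 log2 and BIRC5 was 2.67-fold lower. Mesenchymal and matrix genes had 18 of 43 lower and 8 higher (19 and 8 adjusted over the list alone; median -0.30; adjusted p = 0.186 with an estimated correlation), with FOSL1, an AP-1 subunit, 9.95-fold lower and PLAU, the urokinase, 5.91-fold lower. MYC and ribosome biogenesis genes had 3 of 29 higher and 8 lower (0.171), glial and neural progenitor genes 4 of 29 higher and 5 lower (0.989), and housekeeping genes 1 of 14 higher and 1 lower (0.828). MYC (-0.12) and DRD2 (-0.24) did not pass.

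In total 6278 genes passed for romidepsin, 3191 higher and 3087 lower, with 2291 changed at least 2-fold. Of 42 named genes past the threshold, 41 passed with any 1 array left out, and the 15 lists called by camera kept their calls in each alternative other than the estimated correlation (adjusted p up to 0.041).

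Against each other, the single-drug responses had a correlation across genes of r = 0.229, where genes are not independent replicates. Unchanged groups that share the same 2 DMSO arrays gave a mean of 0.501 in 100 simulations (0.485 to 0.514). Drug changes add spread that these simulations lack. Therefore r and the share of equal signs cannot be compared with them directly, whereas the covariance can. The covariance was 0.0376 against a simulated 0.0167, a difference of 0.0209. The same sign was seen in 61.2% of genes, against 66.7% in the simulations. Of the ONC206 calls, 105 genes were higher with each drug alone and 106 lower with each alone, where independent lists would share 29.3 and 15.6. Another 63 genes were higher with ONC206 and lower with romidepsin (28.3 for independent lists), and 11 were lower and then higher (16.1). The numbers for independent lists take every gene as equally likely to be called. Romidepsin called 215 of 6272 genes at up to 2 log2 on the ONC206 arrays, but 2180 of 4347 at 6 to 8. These numbers are therefore low as a reference, and sharing above them does not by itself link the responses. Of the 63 genes, 16 were interferon-stimulated, IFIT2 and IFIT3 among them. With 1 DMSO array for ONC206 and the other for romidepsin, a split added after the data were examined, r was 0.0725 and 0.0831, and 51.2% of genes had the same sign either way. Of the genes higher with ONC206 in these splits, 30 of 64 and 24 of 47 were also higher with romidepsin (4.87 and 4.06 for independent lists), and of the lower genes, 6 of 6 and 5 of 8 were also lower.

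The third comparison asked what the combination does against DMSO. It was close in its calls to romidepsin alone: of the 3191 genes higher with romidepsin, 2620 (82.1%) were also higher with both drugs, and of the 3087 lower genes, 2670 (86.5%) were lower. These contrasts share the DMSO arrays, and independent lists would share 368 and 365 genes. With 1 DMSO array for each contrast, 72.2% and 80.4% of the higher genes and 81.2% and 76.4% of the lower genes were shared (1783 and 1746 higher, against 214 and 191 for independent lists). Interferon-stimulated genes had 31 of 39 lower and 1 higher (33 and 2 adjusted over the list alone; median -2.23; adjusted p = 0.165 with an estimated correlation), with IFI44L at least 23.6-fold, MX1 21.6-fold, OAS2 20.1-fold and XAF1 18.5-fold lower. CCL2, a monocyte chemokine, was at least 25.1-fold lower (-4.65 ± 0.21; adjusted p = 2.01e-05). Named rises were those of TUFT1 (4.73 ± 0.11), STC1 (4.61 ± 0.24), SLC17A7 (at least 4.48 ± 0.17) and CRISPLD2 (at least 4.17 ± 0.14). Leukocyte markers had a median of -0.06 with 1 of 19 higher and 2 lower, endothelial markers -0.03 with 1 of 14 lower, and pericyte markers 0.13 with 4 of 11 higher and 2 lower.

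Stress response targets had 21 of 53 higher and 8 lower with the combination (23 and 9 adjusted over the list alone), with a median of 0.26 (adjusted p = 0.00131, and adjusted p = 0.165 with an estimated correlation). DDIT3 rose at least 12.5-fold (3.65 ± 0.17) and SLC7A5 7.48-fold (2.90 ± 0.11). NRF2 targets had 10 of 24 higher and 3 lower (13 and 4 adjusted over the list alone; median 0.34; adjusted p = 0.165 with an estimated correlation). G2/M and mitosis genes fell in 55 of 59 cases (57 adjusted over the list alone; median -1.29; adjusted p = 0.107 with an estimated correlation), among them the kinase AURKA (-2.41 ± 0.12) and the cyclin CCNB1 (-2.15 ± 0.13). DNA replication genes had 31 of 46 lower and 3 higher (34 and 4 adjusted over the list alone; median -0.88; adjusted p = 0.165 with an estimated correlation), with TYMS 12.3-fold and E2F8, a repressor of the E2F family, 3.52-fold lower. Homologous recombination genes had 16 of 20 lower and 1 higher, and replication-dependent histones 22 of 42 lower and 5 higher (adjusted p = 0.165 and adjusted p = 0.241 with an estimated correlation). Genes known to rise under HDAC inhibition had 19 of 29 higher and 1 lower (median 0.94), a call that held with an estimated correlation (adjusted p = 0.0477), with DHRS2 up at least 17.2-fold and CPA4 up 12.6-fold.

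CLPP was 2.38-fold lower with the combination (-1.25 ± 0.12), and CLPX 1.38-fold lower (-0.47 ± 0.11), the latter a call that ended without any single DMSO or combination array (adjusted p up to 0.112 without the first combination array). HDAC3 rose 3.98-fold and HDAC1 1.35-fold (0.44 ± 0.12), a call that ended without any single array (adjusted p up to 0.169 without the first DMSO array). CDKN1A rose 2.93-fold. XBP1 (-1.92 ± 0.11) was lower and ERN1 (at least 1.57 ± 0.17) higher within endoplasmic reticulum chaperones (6 of 29 higher, 5 lower, adjusted p = 0.918). Among mitochondrial chaperones 7 of 19 rose and 3 fell (adjusted p = 0.1), with OMA1 at 1.35 ± 0.17. Respiratory chain subunits had 11 of 69 higher and 13 lower (adjusted p = 0.644), with NDUFA9 at -1.22 and ATP5PD at 1.09. Mitochondrial ribosomal proteins had 7 of 72 higher and 20 lower (10 and 23 adjusted over the list alone; median -0.15; adjusted p = 0.597 with an estimated correlation), with MRPL15 at -1.32 and MRPL3 at -1.27. Tricarboxylic acid cycle genes had 12 of 23 higher and 5 lower (median 0.44; adjusted p = 0.165 with an estimated correlation), and cholesterol genes 10 of 18 higher (median 0.60; likewise 0.165). Glycolysis had 7 of 21 higher and 4 lower without a call (adjusted p = 0.107), with SLC2A3 up 10.1-fold and ENO2 3.41-fold, and fatty acid oxidation 5 of 24 higher and 4 lower (adjusted p = 0.749). FAS (-1.82) and CASP8, the initiator caspase, (-1.75) fell within pro-apoptotic genes, of which 7 of 22 rose and 7 fell (adjusted p = 0.896). CFLAR (by at least 2.33) and BIRC5 (-1.51) fell within anti-apoptotic genes, of which 6 of 13 fell and 1 rose (median -0.55; adjusted p = 0.165 with an estimated correlation).

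Neuronal genes had 16 of 40 higher and 1 lower with the combination (median 0.34), among them GRIA2 (at least 2.51) and SCG2 (at least 2.32), and autophagy genes 14 of 27 higher and 1 lower (median 0.48). Both calls were lost with an estimated correlation (adjusted p = 0.165 for each), as were those of metallothioneins (4 of 9 higher, 1 lower; adjusted p = 0.165) and HLA class I genes (3 of 15 higher, 8 lower; adjusted p = 0.165). Mesenchymal genes had 16 of 43 lower and 7 higher (adjusted p = 0.226 with an estimated correlation), with FOSL1 13.5-fold and PLAU 6.69-fold lower. No camera call was made for p53 targets (9 of 28 higher, 5 lower), histone deacetylases (7 of 18 higher, 3 lower), heat shock genes (8 of 20 higher, 2 lower), MYC and ribosome biogenesis genes (3 of 29 higher, 8 lower), glial genes (3 of 29 higher, 6 lower) or housekeeping genes (2 of 14 higher, 1 lower). DRD2 (0.34), HDAC2 (-0.07), ATF4 (0.40), MYC (0.20) and PPARGC1A (0.68) did not pass. In total 6670 genes passed, 3293 higher and 3377 lower, with 2484 changed at least 2-fold. The calls of mitochondrial ribosomal proteins, the tricarboxylic acid cycle and metallothioneins ended without the second, the first and the first DMSO array (adjusted p = 0.237, 0.0514 and 0.0852), those of the ribosomal proteins and metallothioneins also without the first combination array (0.0851 and 0.068), metallothioneins without either romidepsin array (0.0564), and that of HLA class I genes without dim genes of a mean up to 2.51 log2 (0.0602).

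The fourth comparison asked what ONC206 adds in romidepsin-treated cells. Of the 8 genes that rose, 7 were among the 53 stress response targets (28 rose and 2 fell adjusted over the list alone), with a median of 0.36 (adjusted p = 4.9e-22, and adjusted p = 0.0602 with an estimated correlation). CHAC1, a glutathione-degrading enzyme, rose by a log2 change of 2.58 ± 0.11 (adjusted p = 0.000559), DDIT3 4.42-fold (2.15 ± 0.17), SESN2 4.17-fold (2.06 ± 0.20) and NUPR1 2.52-fold (1.34 ± 0.14). IFIT2 rose at least 6.19-fold (2.63 ± 0.18; adjusted p = 0.0118). It was the 1 of 39 interferon-stimulated genes past the threshold, with 5 members higher and 5 lower at an unadjusted p under 0.05 and a list median of -0.10 (adjusted p = 0.951). IFIT3, chosen after its values were seen, had a change of 2.09 ± 0.23 that did not pass (adjusted p = 0.0749). The other genes past the threshold, chosen after their values were seen, were HERPUD1 (1.32), PSAT1 (1.17) and SLC7A11 (1.08), all stress response targets, and the non-coding RNA LINC02104 (at least 1.35 lower). All 8 genes that rose were also higher with ONC206 against DMSO. ATF4 had a change of 0.79 ± 0.15 (adjusted p = 0.237).

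In total 9 genes passed for ONC206 in romidepsin-treated cells. The count depended on every array: it was 4 without either DMSO array, 3 without either ONC206 array and 1 without any of the romidepsin or combination arrays. CHAC1 passed in each of these fits, while the highest adjusted p of DDIT3 was 0.279, of IFIT2 0.236, and of SESN2 and NUPR1 0.394. The camera call of the tricarboxylic acid cycle (median -0.15; adjusted p = 0.0496, 3 of 23 members at an unadjusted p under 0.05) was lost with an estimated correlation (adjusted p = 0.74) and in 10 of 13 other alternatives, among them the removal of any array but the second romidepsin array (up to adjusted p = 0.225 without the first romidepsin array). No other list was called. p53 targets (SESN2) and NRF2 targets (SLC7A11) each had 1 gene higher, both of them stress response targets. In the other lists limma called 0 members, with 2 of 59 genes of G2/M and mitosis and 2 of 46 of DNA replication at an unadjusted p under 0.05 and medians of -0.02 and 0.07. Leukocyte, endothelial and pericyte markers had medians of 0.07, 0.02 and -0.16. CLPP (-0.17), CLPX (-0.31), DRD2 (0.58), HDAC1 (-0.23), HDAC2 (-0.05), HDAC3 (0.13), CDKN1A (0.09), MYC (0.33) and PPARGC1A (-0.22) did not pass.

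**Figure D2:**
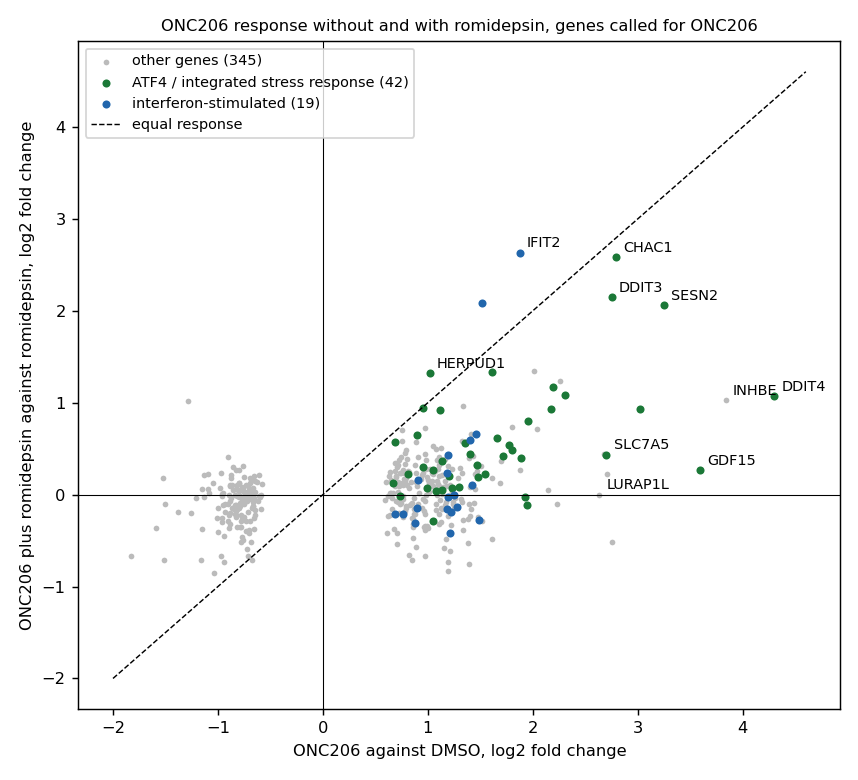
Log2 fold change of ONC206 against DMSO (horizontal axis) and of ONC206 plus romidepsin against romidepsin (vertical axis) for the 406 genes past the threshold in the former, 1 dot per gene, with 42 stress response targets in green, 19 interferon-stimulated genes in blue and a dashed line of equal response. Most genes lie near 0 on the vertical axis, while CHAC1 (2.79 and 2.58) lies near the line and IFIT2 (1.87 and at least 2.63) above it.

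The fifth comparison asked what romidepsin adds in ONC206-treated cells. Interferon-stimulated genes fell in 36 of 39 cases (37 adjusted over the list alone), with a median of -3.41 (adjusted p = 0.111 with an estimated correlation). MX1 was 58.8-fold lower (-5.88 ± 0.28), IFI44L at least 57.1-fold (-5.84 ± 0.14, to a combination mean of 2.42), XAF1 51.8-fold (-5.69 ± 0.14), OAS2 45.4-fold and IFITM1, a membrane protein that blocks viral entry, 34.5-fold. HLA class I genes had 9 of 15 lower and 1 higher (median -1.08; adjusted p = 0.0999 with an estimated correlation). Leukocyte markers had a median of 0.01 with 2 of 19 lower, endothelial markers -0.02 with 1 of 14 lower and pericyte markers 0.08 with 3 of 11 higher and 1 lower. Stress response targets were lower than with ONC206 alone in 36 of 53 cases and higher in 5 (38 and 5 adjusted over the list alone), with a median of -0.95 (adjusted p = 0.0912 with an estimated correlation), and SLC6A9, a glycine transporter, was 10.9-fold lower (-3.44 ± 0.11). DDIT3 was among the higher ones (0.90 ± 0.17; adjusted p = 0.0552 without the second combination array). NRF2 targets had 11 of 24 lower and 4 higher (median -0.44; adjusted p = 0.169 with an estimated correlation).

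Named rises were those of STC1, 69.4-fold (6.12 ± 0.24), SLC17A7 (at least 5.01 ± 0.17), TUBB4A (at least 4.37 ± 0.24) and the pseudogene CEACAM22P (at least 4.15 ± 0.27). Genes of G2/M and mitosis fell in 43 of 59 cases (median -0.75; adjusted p = 0.111 with an estimated correlation), AURKA by 1.63 on the log2 scale. DNA replication genes had 17 of 46 lower and 7 higher (median -0.25; adjusted p = 0.588 with an estimated correlation), with TYMS at -2.81. Homologous recombination genes had 8 of 20 lower and 2 higher (adjusted p = 0.439 with an estimated correlation), and histones 13 of 42 lower and 6 higher (adjusted p = 0.61). Genes known to rise under HDAC inhibition had 18 of 29 higher and 1 lower (median 0.91; adjusted p = 0.0624 with an estimated correlation), with DHRS2 at least 3.97 higher. Neuronal genes had 16 of 40 higher and 2 lower (median 0.43; adjusted p = 0.111 with an estimated correlation), with GRIA2 at least 2.72 higher. Cholesterol genes had 12 of 18 higher (median 0.91; adjusted p = 0.112), heat shock genes 7 of 20 higher and 1 lower (adjusted p = 0.112), tricarboxylic acid cycle genes 12 of 23 higher and 3 lower (adjusted p = 0.125), anti-apoptotic genes 6 of 13 lower and 1 higher (adjusted p = 0.125), metallothioneins 4 of 9 higher and 1 lower (adjusted p = 0.221), glycolysis 5 of 21 higher and 2 lower (adjusted p = 0.258), mesenchymal genes 16 of 43 lower and 6 higher (adjusted p = 0.258) and autophagy genes 12 of 27 higher and 2 lower (adjusted p = 0.344), each p with an estimated correlation and each list called with the preset one.

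Among the remaining named genes, CLPP was 2.33-fold lower (-1.22 ± 0.12), CLPX 1.60-fold lower, XBP1 7.48-fold lower, FAS 3.46-fold lower, CFLAR at least 4.99-fold lower, FOSL1 9.75-fold lower and MRPL15 2.50-fold lower. HDAC3 was 4.03-fold higher, HDAC1 1.51-fold, CDKN1A 1.91-fold, PPARGC1A 1.77-fold, SLC2A3 6.49-fold, TIMM17A 2.45-fold and NDUFB3 2.63-fold. MYC fell by 0.51, a call that ended without any single ONC206 or combination array (adjusted p up to 0.0645 without the first combination array). The HDAC1 call ended without the second ONC206 or the first combination array (0.069 and 0.0675), and that of PPARGC1A without the first ONC206 or the second combination array (0.146 and 0.16). DRD2 (0.02), HDAC2 (0.09) and ATF4 (-0.26) did not pass. No camera call was made for endoplasmic reticulum chaperones (10 of 29 higher, 4 lower), mitochondrial chaperones (8 of 19 higher, 5 lower), respiratory chain subunits (10 of 69 higher, 8 lower), mitochondrial ribosomal proteins (6 of 72 higher, 18 lower) or fatty acid oxidation (5 of 24 higher, 6 lower). The same holds for p53 targets (6 of 28 higher, 9 lower), pro-apoptotic genes (6 of 22 higher, 5 lower), histone deacetylases (7 of 18 higher, 2 lower), MYC and ribosome biogenesis genes (2 of 29 higher, 6 lower), glial genes (5 of 29 higher, 6 lower) and housekeeping genes (2 of 14 higher, 1 lower). In total 6443 genes passed, 3174 higher and 3269 lower, with 2334 changed at least 2-fold. The calls of DNA replication and histone genes ended without the second ONC206 array (adjusted p = 0.0716 for each). Those of homologous recombination genes and metallothioneins ended with quantile normalization again (adjusted p = 0.0762 for each). The repair call also ended without the first ONC206 or the second combination array (up to 0.055), and the metallothionein call without either DMSO, either romidepsin or the first combination array (up to 0.0638).

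The last comparison asked whether the log2 changes of the drugs add up. For 15 genes they did not, and in each the ONC206 response was lower in romidepsin-treated than in DMSO-treated cells. This single direction was not seen with trend and robust fitting (193 above and 294 below 0), without dim genes (20 and 91), with median centring (1 and 28) or without the second ONC206 array (1 and 2). GDF15 had an interaction of -3.33 ± 0.31 (log2; adjusted p = 0.026): its mean level was 4.13 ± 0.53 with DMSO, 7.72 ± 0.08 with ONC206, 6.47 ± 0.01 with romidepsin and 6.73 ± 0.01 with both (SD, n = 2). DDIT4 had an interaction of -3.23 ± 0.19 (adjusted p = 0.00784), with levels of 4.18 ± 0.21, 8.48 ± 0.04, 5.58 ± 0.11 and 6.65 ± 0.01 in the same order. INHBE (-2.81 ± 0.25), LURAP1L (-2.63 ± 0.20) and NIBAN1 (-2.33 ± 0.16), a stress-induced regulator of translation, followed. Of 53 stress response targets 5 had an interaction below 0 (35 adjusted over the list alone), with a median of -0.95, and of 24 NRF2 targets 2 (20 adjusted over the list alone), with a median of -1.03. Both calls held with an estimated correlation (adjusted p = 0.015 for each). DDIT3 (-0.61 ± 0.25; adjusted p = 0.434) did not pass.

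Interferon-stimulated genes had a median interaction of -1.04 (adjusted p = 1.68e-25, and adjusted p = 0.125 with an estimated correlation). limma called 0 of 39, with 34 at an unadjusted p under 0.05 and 32 below 0 adjusted over the list alone, and XAF1 was the nearest (-1.76 ± 0.20; adjusted p = 0.0546). Leukocyte, endothelial and pericyte markers had medians of 0.05, -0.03 and -0.07. The interaction of proliferation genes lay above 0, since the falls with ONC206 were smaller in romidepsin-treated cells. limma called 0 of 46 genes of DNA replication (39 at an unadjusted p under 0.05, and 39 adjusted over the list alone; median 0.67) and 0 of 59 of G2/M and mitosis (45 at an unadjusted p under 0.05, and 43 adjusted over the list alone; median 0.59). Both list calls held with an estimated correlation (adjusted p = 0.047 for each), and the members with the smallest p were CDC6 (1.21 ± 0.16) and MKI67 (1.21 ± 0.15), each with an adjusted p = 0.0547. p53 targets (median -0.35; 0 of 28 called, 11 at an unadjusted p under 0.05) and HLA class I genes (median -0.29; 0 of 15 called, 6 at an unadjusted p under 0.05) were called as lists too (adjusted p = 0.047 for each with an estimated correlation). Homologous recombination genes (median 0.52; adjusted p = 0.0978 with an estimated correlation), histones (0.41; adjusted p = 0.303), cholesterol genes (0.30; adjusted p = 0.372), endoplasmic reticulum chaperones (0.14; adjusted p = 0.328) and mitochondrial chaperones (-0.11; adjusted p = 0.192) lost their calls. The targets CLPP (-0.14), CLPX (-0.52), DRD2 (0.26), HDAC1 (-0.08), HDAC2 (0.11), HDAC3 (0.15), ATF4 (0.13), CDKN1A (-0.53), MYC (-0.39) and PPARGC1A (-0.08) did not pass.

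The ONC206 response in romidepsin-treated cells was uneven within the stress response list. The 262 genes raised by ONC206 had a median log2 change of 1.07 in DMSO-treated and 0.11 in romidepsin-treated cells, and the 144 lowered genes -0.80 and -0.07, with the genes selected on the first of these values. Of the raised genes 159 kept their sign and 259 had a smaller value. As a share of the change in DMSO-treated cells, CHAC1 kept 92.7%, DDIT3 at most 78.0% and SESN2 63.4%, against 24.9% for DDIT4, 16.1% for SLC7A5, 7.40% for GDF15 and -5.82% for SLC6A9 (these 7 among 42 raised targets were chosen after their values were seen). With romidepsin alone, DDIT4, SLC7A5 and GDF15 had log2 changes of 1.40, 2.47 and 2.34, and SLC6A9 -1.39. A small share kept therefore need not mean a lower level with both drugs: SLC7A5 was 0.20 higher than with ONC206, and SLC6A9 3.44 lower.

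The 15 calls of the interaction depended on every array. The count was 2 and 7 without the first or the second DMSO array, 0 and 3 without either ONC206 array, 7 and 0 without either romidepsin array, and 0 without either combination array, each by limma, with 2526 to 2857 genes at an unadjusted p under 0.05 where it was 0. Over these fits the highest adjusted p was 0.173 for GDF15, 0.0899 for DDIT4, 0.159 for INHBE, 0.097 for LURAP1L and 0.0899 for NIBAN1. The 9 list calls for stress response, NRF2, interferon, proliferation, repair, histone, p53 and HLA genes remained in each alternative other than the estimated correlation (adjusted p up to 0.00182). Those of endoplasmic reticulum chaperones and cholesterol genes ended without the second DMSO array (adjusted p = 0.214 and 0.067). The former ended without every other array but the first DMSO array as well (up to 0.068). That of mitochondrial chaperones ended without the first romidepsin, the first DMSO or the second ONC206 array (0.0827, 0.0759 and 0.0557).

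**Figure D3:**
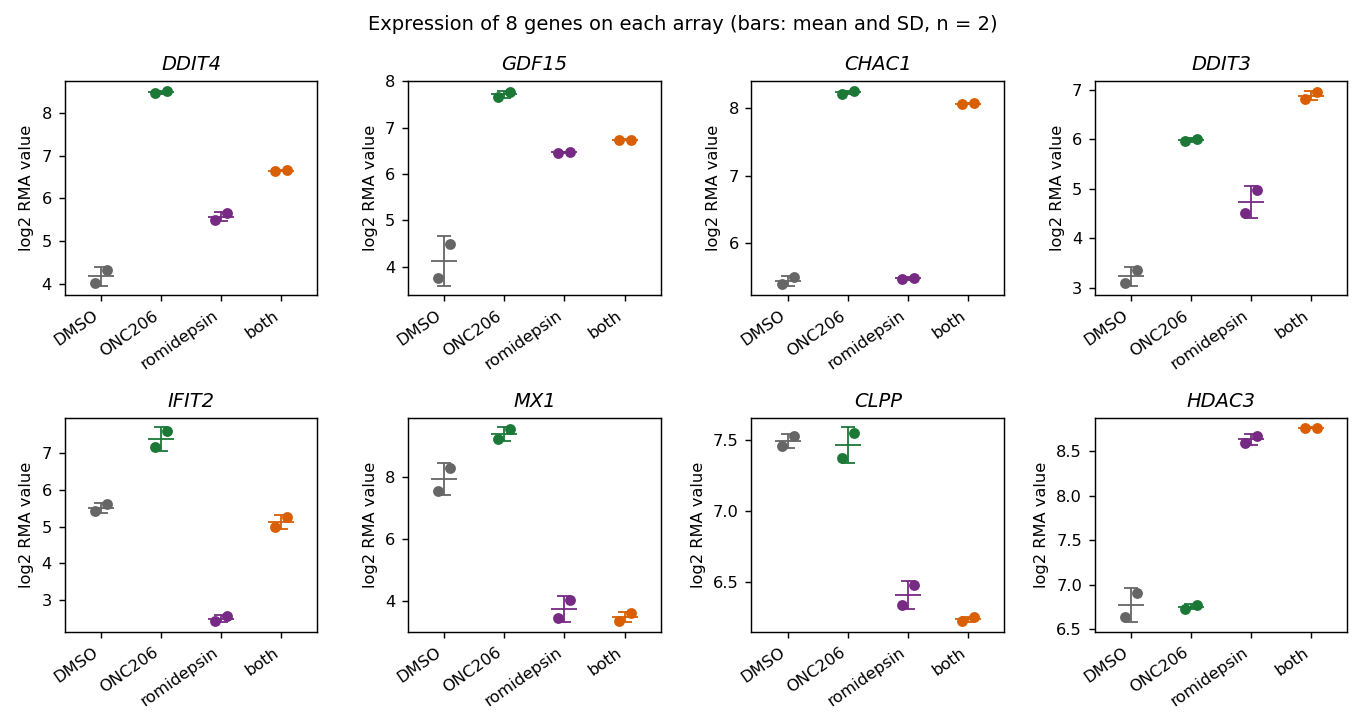
Log2 RMA value (vertical axes) of 8 genes in the 4 treatment groups (horizontal axes), with 1 dot per array and bars at the mean and SD of the 2 arrays. DDIT4 fell from 8.48 with ONC206 to 6.65 with both drugs while DDIT3 rose from 5.98 to 6.88, MX1 was at 3.75 with romidepsin, and CLPP was at 6.41 with romidepsin against 7.49 with DMSO.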

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

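The tests of a ceiling of the array scale, of leukocyte RNA and of a batch confined to 1 group were chosen only after the results were seen, whereas those of a common factor, of a combination array without ONC206 and of a single array were written down before their values were computed.

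A difference between groups stood out in the interaction test, where limma called 15 genes whose ONC206 response differed with romidepsin. Their log2 interactions were -3.33 for GDF15, -3.23 for DDIT4, -2.81 for INHBE, -2.63 for LURAP1L and -2.33 for NIBAN1. They were -2.27 for SLC7A5, -2.24 for RAB39B, -2.15 for BLTP3A, -2.10 for TIMP4, -2.09 for HMOX1, -2.06 for SLC6A9, -1.83 for ABCC3, -1.80 for STK32A, -1.64 for NCOA7 and -1.49 for CEBPB. The last 10 are named because they complete the count, after their values were seen. These genes took different courses. SLC7A5, HMOX1 and RAB39B rose with each drug alone (log2 changes of 2.70 and 2.47, 2.15 and 2.44, and at least 2.68 and 2.46) and were only 0.20, 0.35 and 0.22 higher with both drugs than with ONC206. DDIT4, INHBE, NIBAN1 and SLC6A9 were lower with both drugs than with ONC206 (-1.83, -2.93, -2.42 and -3.44).

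As lists, the median interactions were -0.95 for stress response targets, -1.03 for NRF2 targets, -1.04 for interferon-stimulated genes, -0.35 for p53 targets, -0.29 for HLA class I genes and -0.11 for mitochondrial chaperones and proteases. They were 0.67 for DNA replication, 0.59 for G2/M and mitosis, 0.52 for homologous recombination, 0.41 for replication-dependent histones, 0.30 for cholesterol synthesis and 0.14 for endoplasmic reticulum chaperones. With an estimated correlation, 6 of these 12 camera calls held. Those of interferon-stimulated genes, homologous recombination, histones, cholesterol synthesis and both chaperone lists were lost.

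The weaker rise of stress response targets under romidepsin was weighed against 3 explanations. Of these, a single common factor, by which every ONC206 response was weaker, need not be technical. A ceiling of the array scale would leave the targets as high with both drugs as with ONC206. The 42 raised targets had a median change of -1.09 from ONC206 to both drugs (SE 0.142 over targets, which are not independent replicates), and 37 were lower. They were selected as raised on the ONC206 arrays, which by itself lowers this median. Over all 53 measured targets the mean was 8.23 with ONC206 and 7.37 with both drugs. The fifth comparison had already shown this fall, so the test restates it. A single common factor was estimated at 0.165, and 13.3% of the 406 genes (54) deviated from it, 25 keeping more and 29 less. In simulated data with a true common factor of 0.3, 0.639% deviated. Those simulated genes varied independently and had no romidepsin effect, so their share is not an exact reference for these data. A combination array from cells without ONC206 would set its pair apart, but the combination arrays differed by 7.92% of the rise they shared (0.05 of 0.59 log2). Other explanations were not tested for this pattern and stay open, a loss of ONC206 action through its target among them. CLPP RNA was lower with romidepsin (-1.08), while ClpP protein and its activity were not measured here.

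For the rise of interferon-stimulated genes with ONC206 and their fall with romidepsin, leukocyte markers had medians within 0.103 log2 of 0 in both contrasts. Their median level with DMSO was 2.42, against 3.38 for all genes, so they had little room to fall. The markers could have risen with ONC206 (median -0.01), but their flat median cannot speak to the fall with romidepsin. Without any single array, at least 74.7% of the median changes of the interferon list was left (0.76 with ONC206 and -2.15 with romidepsin at the least). Replicates differed by up to 0.35 log2 in the list mean, against 1.03 between ONC206 and DMSO and -2.14 between romidepsin and DMSO. A batch confined to 1 group and behind the fall would lower the list in only 1 of the romidepsin contrasts that share no array. The medians were -2.15 against DMSO and -3.41 with both drugs against ONC206. This test cannot speak to the rise with ONC206, since a batch confined to the ONC206 arrays was not tested. The labels name no batch, so none was weighed beyond this one.

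Probe sets without gene names passed in shares near those of named genes. Of 1041 unnamed probe sets, 15 (1.44%, against 1.42% of named genes) passed for ONC206 against DMSO, 238 (22.9% against 22.0%) for romidepsin against DMSO and 263 (25.3% against 23.4%) for the combination against DMSO, and what they measure was not analysed here.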

How the results depend on the processing

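Of the named genes and lists, 0 past the threshold turned direction under any alternative. Centring on array medians gave 5 genes for ONC206 added to romidepsin and 29 for the interaction. Without dim genes, ONC206 against DMSO gave 641 and the interaction 111. With trend and robust fitting they gave 1334 and 487, and ONC206 added to romidepsin 155. A fit of the compared groups alone, which has 2 residual degrees of freedom, gave 50 for ONC206 and by limma 0 for ONC206 added to romidepsin, with 2732 at an unadjusted p under 0.05. The replicate number as a block gave 208 for ONC206, 2 for ONC206 added to romidepsin and 9 for the interaction. Deviations from group means correlated at -0.0509 to -0.00174 between groups, so arrays of the same number shared no deviation across genes. Whether a number marks a shared culture or day is not given by the labels and stays unknown. Requiring a log2 change of at least 1, which removes genes by construction, left 165 for ONC206, 2291 for romidepsin, 2484 for the combination against DMSO and 2334 against ONC206. With each array left out, counts ran from 52 to 241 for ONC206, 1 to 4 for ONC206 added to romidepsin and 0 to 7 for the interaction (2526 or more at an unadjusted p under 0.05 each time). They ran from 4507 to 5817 for romidepsin, 4789 to 6376 for the combination against DMSO and 4391 to 6271 against ONC206. Only the split of the DMSO arrays between the contrasts was added after the data were examined, and it gave correlations of 0.0725 and 0.0831 for the single-drug responses, without the shared controls by construction. With arrays left out, this correlation ran from 0.203 to 0.319, the highest values without the first or the second DMSO array (0.319 and 0.309). Fewer arrays lower the counts by construction, and for the other alternatives the cause was not tested. Of 3491 comparisons of a named gene with an alternative, 3251 stayed on their side of the threshold, 205 lost and 35 gained a call. For lists it was 2526, 129 (65 of them with an estimated correlation) and 33. Values called in neither setting changed sign in 142 comparisons. The share of higher genes among the ONC206 calls was 64.5%, 49.6% with trend and robust fitting, 56.8% without dim genes, 61.2% with quantile normalization, 71.3% with median centring, 77.9% with the block, 87.9% with the log2 change of at least 1, 94.0% in a fit of the compared groups alone and 72.6% to 91.5% with an array left out.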

Other observations

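The tests of gene families, the genes named in this part and the spread of the baseline pattern over left-out arrays were chosen only after values were seen, whereas both tests of that pattern were written down before their values were computed.

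Romidepsin lowered clustered protocadherins of the beta group, cell adhesion proteins of neurons: 13 of 14 PCDHB genes fell, with a median log2 change of -1.41, against 18.2% of the 14523 genes that served as background (hypergeometric test over 196 symbol families, adjusted p = 1.09e-06). These paralogs are alike in sequence, and probe sharing was not examined. Their values may therefore not be separate measurements, as the hypergeometric test takes them to be. The count stayed at 13 under both other scalings of the arrays, where 0 medians of the families turned. Symbols of H and a digit, which histone genes carry, had 24 of 51 lower (median -0.43, adjusted p = 0.000443). The higher members of this family are not given here, and it was not run under the other scalings. MCM symbols, among them the genes of the replicative helicase, had 8 of 10 members lower (median -1.37, adjusted p = 0.00499). PARP genes of ADP-ribosylation had 8 of 12 lower with 1 higher (median -1.34, adjusted p = 0.0266), and KIF kinesins 16 of 37 with 6 higher (median -0.18, adjusted p = 0.0266). Members of a family may be regulated together, which the hypergeometric test does not allow for. ATP genes, mostly ion pumps and ATP synthase subunits, had 26 of 72 higher and 6 lower (36.1% against 18.8% higher, adjusted p = 0.0266), and STX syntaxins of vesicle fusion 8 of 13 higher and 2 lower (adjusted p = 0.0454). With ONC206, 3 of 10 MCM genes and 4 of 37 KIF genes fell (adjusted p = 0.0185 and 0.0434), and 4 of 16 ALDH genes, which oxidise aldehydes, rose (adjusted p = 0.0185). With median centring the higher ATP and STX genes were 24 and 7, and with quantile normalization the higher ALDH genes were 3, while the lower MCM, PARP and KIF genes with romidepsin stayed at 8, 8 and 16.

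Single genes are given next, without a test of the groups they belong to. With romidepsin, TUBB2B, a neuronal beta-tubulin, rose 16.5-fold (4.04 ± 0.11), and TUBB3 (0.65), TUBA1A (0.67) and TUBA4A (at least 0.78) rose less, while TUBB (-1.18 ± 0.14) and TUBB6 (-1.43 ± 0.11) fell. The chemokine gene CCL20 rose by 3.39 ± 0.22, while CCL2 was 8.80-fold lower (-3.14 ± 0.21) and CXCL10 was lower by at least 1.38 ± 0.18. CD274, the immune checkpoint ligand PD-L1, rose by at least 1.01 ± 0.28 (limma, adjusted p = 0.0366), while IFNGR2, a chain of the interferon gamma receptor, and CIITA, the activator of HLA class II genes, had changes of -1.23 and -1.20. ONC206 raised IL20RB, a cytokine receptor chain, 3.48-fold (1.80 ± 0.14).

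The romidepsin change was lower for genes of higher baseline, here taken as the mean of the ONC206 arrays. Of 1078 called among 10549 genes at 2 to 4 log2, 68.6% rose. Of 645 called among 1230 genes at 8 to 10, 33.2% rose. The median changes over all genes in these ranges were small, at -0.01 and -0.13. Genes near the floor of the scale have little room to be called lower, which by itself raises the former share. Regression to the mean through the shared DMSO arrays would remove the trend when the baseline comes from the ONC206 arrays, but the rank correlation of baseline and change was -0.0749 then, against -0.115 with the DMSO baseline. The array scale or the normalization would give ONC206 a like trend, and its rank correlation with the romidepsin baseline was -0.0306, under 0.5 of the former value (-0.0375) by about 1 SE (0.00592, which treats genes as independent). With each array left out it ran from -0.0790 to 0.0145 and reached 0.5 of the romidepsin value in 3 of 8 cases, so this explanation stays open and cannot be told apart from an effect of romidepsin.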
